A study of Zea mays with 9 samples.

How the data were processed

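Chromatin accessibility was measured by ATAC-seq, in which a transposase loaded with sequencing adapters inserts into open DNA, so that reads pile up at accessible sites. Per the labels, nuclei came from flash-frozen roots of maize B73 seedlings given tunicamycin, and libraries were made at 0 h, 6 h and 12 h. Each time point had 3 libraries, which the series describes as biological replicates. How far apart they were prepared is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical. One label calls the material protoplasts and others call it root, and the root labels are followed here because the extraction protocol also names root. The treatment label gives 5 mg per ml tunicamycin in DMSO without saying whether that is a stock or a final concentration. No untreated libraries at 6 h or 12 h were analysed here, so time in the drug and time itself vary together.

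The authors deposited a table of whole-number coverage values for 38703 gene identifiers in 9 libraries, with 0 columns that belong to no sample. Reads were handled with cutadapt 1.11, Bowtie2 2.2.6, MACS2 and DESeq2, per the submitters' processing notes, which give no role or order for them. The genome build, the window counted around each gene, any shift of reads for the transposase and any removal of duplicate or organellar reads are not given in the sources used here. Those steps could change the values, since a wide window adds reads from closed chromatin and duplicates add reads that are not independent.

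The values were taken as coverage in read bases, not read counts, because of their steps. Low values piled up on multiples of 73. The value 73 itself was seen 5648 times against a mean of 48.5 times for its neighbouring whole numbers, and the value 365 was seen 5093 times, 31.5 times as often as its neighbours. Depending on the library, between 16.6% and 22.6% of the values above 0 were exact multiples of 73, where an even spread would give 1.37%. On that reading, a read overlapping a window in full added 73, and values between the multiples held reads that overlapped in part. Whether 73 is the length of a sequenced read was not checked, so a read below means a unit of that length. Library totals differed, so the deposited coverage was not scaled to a common total. Totals divided by 73 gave between 396306 and 536001 read equivalents per library. The median gene held 11.0 read equivalents, which limits precision for single genes. PCR copies cannot be told from separate molecules, so all intervals cover sampling error only.

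The count test that had been planned was not used, because coverage is not a count. The planned fallback for other units took its place. Coverage was divided by library scale factors from the trimmed mean of M values, computed from the published formula with 30% of ratios and 5% of levels trimmed at each end. A pseudocount of 1 was added, values were put on the log2 scale, and limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with trended, robust variance moderation. Fold changes are on the log2(value + 1) scale, which distorts the change of low genes. Genes with a mean under 1 in every group were to be dropped, and the minimum removed none. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 38703 genes, with a threshold of 0.05. Simulated coverage for 6 h against 0 h with 38703 genes held 200 changed genes at once, and its replicates differed by read sampling only. The limma step recovered 14 of 67 genes changed 2-fold (20.9%), 46 of 67 changed 4-fold (68.7%) and 43 of 66 changed 8-fold (65.2%). With the changed genes drawn from those of mean coverage 730 or more, which is 10 reads, it recovered 28 of 67 (41.8%), 56 of 67 (83.6%) and 54 of 66 (81.8%), and called 3 unchanged genes.

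Library totals, the share of the 100 highest and correlations between libraries had been planned. The other measures that pool genes were added after the gene tests had been seen. The dispersion of a pair of libraries was the summed squared difference of scaled coverage divided by the sum expected per unit of coverage. It is 73 for independent full reads and lower where reads overlap a window in part. The mean over pairs from different time points minus the mean over pairs from the same time point was compared with all 280 splits of the 9 libraries into 3 groups of 3. The reproducible variance of log2 changes was the covariance, over 21459 genes of mean coverage 730 or more, between 2 changes computed from separate libraries, with a pseudocount of 73, averaged over 18 choices of libraries. Sampling noise that is independent between libraries averages out of such a covariance, but it still scatters the estimate. The 95% interval of the estimate came from 2000 bootstrap samples of 200 blocks of genes. That interval covers the choice of genes but not the choice of libraries. In simulated data with no change the estimates were 0.0003, -0.0012 and -0.0006, and a simulated SD of 0.1 for the changes against 0 h was estimated at 0.091 and 0.088. Group differences in library measures used two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1, with adjustment over 12 tests of pairs of times and separately over 4 tests across all times. Calculations outside R used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.

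The table pairs no gene identifier with a gene name. Of the identifiers, 0 matched the RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0. The 22 gene lists and 13 sequence motifs fixed before the data were examined were therefore not tested, nor were location classes, GC content or organellar sequences. The rule for named genes, also fixed before the data were examined, took the 5 genes of lowest p per direction and comparison where none passed the threshold. It gave 28 genes. Because no names for them were available here, the comparisons print 4 identifiers, those with the 2 lowest p-values in each direction. This narrowing was chosen after their values had been seen. The closing section prints 5 more, which the screen for results to look at again picked out. The screen for results to look at again and the alternatives used all 28. Alternatives covered the scaling, the minimum coverage, the pseudocount, the scale, voom weights, the libraries in the fit, a replicate block and leaving out each library.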

Results

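Accessibility was measured at 38703 maize genes in root nuclei from B73 seedlings at 0 h, 6 h and 12 h of tunicamycin, with 3 libraries at each time. Tunicamycin blocks N-linked glycosylation of proteins in the endoplasmic reticulum, and the series concerns the stress that persistent misfolding causes there. The comparisons ask which genes differed in accessibility after 6 h and 12 h of this stress, and between those times. Total coverage was 39.1, 35.0 and 38.1 megabases in the 0 h libraries, 31.1, 33.1 and 28.9 megabases at 6 h, and 36.8, 36.3 and 35.8 megabases at 12 h. Every gene had coverage in at least 1 library, and between 536 and 718 genes were at 0 in any single library. The median standard error of a gene's log2 change was 0.35, and 0.29 among the 21459 genes with mean coverage of 730 or more.

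Genes at 6 h were first compared with 0 h to find early differences under tunicamycin. No single gene passed the threshold. Zm00001d042506 had the lowest p among genes with less coverage at 6 h. Its scaled coverage was 305 ± 307 (SD, n = 3) at 6 h and 1186 ± 275 (SD, n = 3) at 0 h. The log2 change was -2.46 (SE 0.51), with a limma adjusted p of 0.678. All 3 libraries at 6 h lay below all 3 at 0 h, the highest at 654 and the lowest 0 h value at 875. Without 6 h replicate 1, the library at 654, the log2 change of Zm00001d042506 was -3.28 and its limma adjusted p was 0.00169, and without 6 h replicate 2 they were -1.74 and 0.444. Replicates 2 and 3 at 6 h held 76.0 and 186, the coverage of few reads, where the pseudocount matters. With all libraries and a pseudocount of 73 the log2 change of this gene was -2.03, with a limma adjusted p of 0.0739. Among the 5 genes of lowest p with higher coverage, log2 changes ran from 0.67 to 1.36, and among the 5 with lower coverage from -2.46 to -1.07.

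Of the 38703 genes, limma called 0 at an adjusted p under 0.05 for 6 h against 0 h. At an unadjusted p under 0.05 there were 2365 genes. If no gene changed, 5% of all genes would nominally fall under that level by chance. With voom weights limma also called 0, with 2347 genes at the unadjusted level. On a square-root scale, an alternative added after seeing the data, limma called 1 gene, Zm00001d042506, at an adjusted p of 0.0267. In simulated data of the same size and depth, limma recovered 20.9% of genes changed 2-fold, 68.7% of those changed 4-fold and 65.2% of those changed 8-fold. There 200 genes of these sizes changed together, and replicates differed by read sampling only. Where fewer genes change, the adjustment is stricter, so recovery could be lower than these rates.

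After 12 h, Zm00001d040216 had the lowest p of all genes against 0 h. Its coverage was 251 ± 82.4 (SD, n = 3) at 0 h, 729.9 ± 94.7 (SD, n = 3) at 6 h and 1142 ± 554 (SD, n = 3) at 12 h. The log2 change at 12 h was 2.13 (SE 0.42), with a limma adjusted p of 0.397. Zm00001d051105 was lower at 12 h, with 94.6 ± 50.7 (SD, n = 3) against 587 ± 209 (SD, n = 3) at 0 h. Its log2 change was -2.67 with a limma adjusted p of 0.404, and -1.96 with a pseudocount of 73, its coverage at 12 h being near that of 1 read. Neither gene passed the threshold. The 5 genes of lowest p with higher coverage at 12 h had log2 changes from 1.18 to 2.13, and the 5 with lower coverage from -2.67 to -0.95.

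For 12 h against 0 h, limma called 0 of the 38703 genes at an adjusted p under 0.05. There were 2003 genes at an unadjusted p under 0.05, near the 5% nominally given by chance, while other splits of the same libraries gave at most 1596. With voom weights limma called 0, with 2435 genes at the unadjusted level. On the square-root scale limma called 2 genes, Zm00001d040216 and Zm00001d019241, both at an adjusted p of 0.047.

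Between 6 h and 12 h, Zm00001d019241 had 1022 ± 176 (SD, n = 3) at 6 h and 2436 ± 161 (SD, n = 3) at 12 h. The log2 change was 1.27 (SE 0.25), with a limma adjusted p of 0.287. Its 0 h coverage was 1097 ± 271 (SD, n = 3), and its log2 change from 0 h to 6 h was -0.09, with a limma adjusted p of 0.98. Each of the 3 libraries at 12 h had at least 2261, above the highest value of 1312 in the other 6. Zm00001d051105 had 714 ± 298 (SD, n = 3) at 6 h against its 94.6 ± 50.7 (SD, n = 3) at 12 h. That log2 change was -2.95 (SE 0.56), with a limma adjusted p of 0.276, the lowest in this comparison, and with a pseudocount of 73 it was -2.21.

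**Figure D1:**
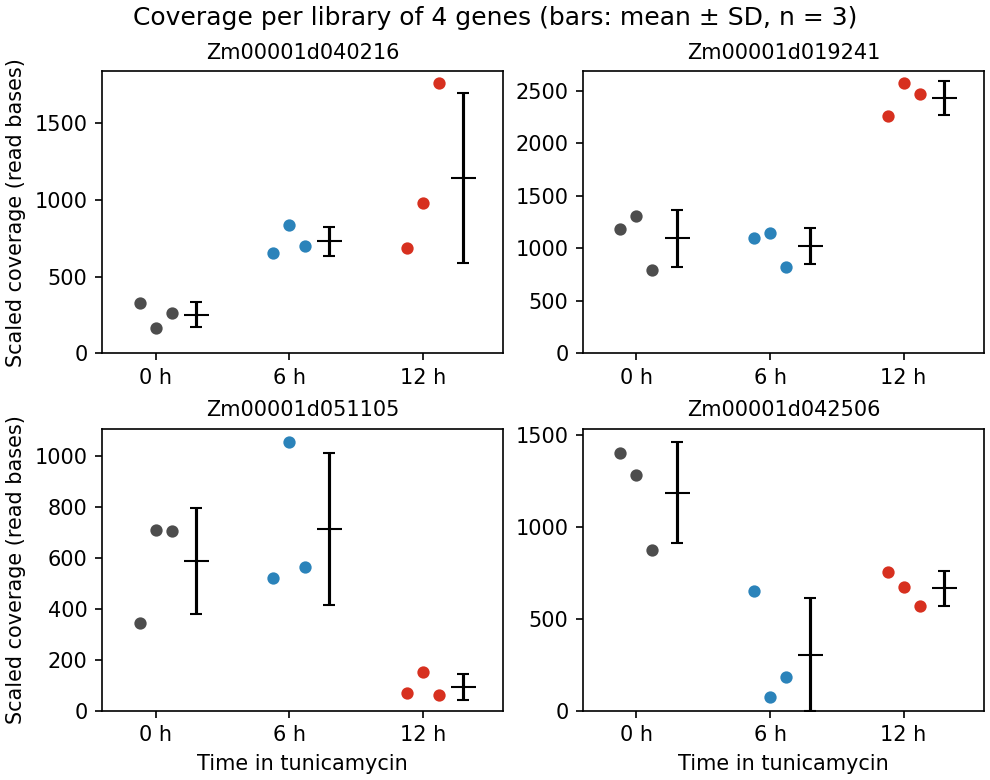
Scaled coverage in read bases (y axis, linear from 0) of 4 genes in each library at 0 h, 6 h and 12 h of tunicamycin (x axis), with points for libraries and bars for the mean ± SD of 3. Zm00001d019241 had at least 2261 in each 12 h library, and 3 of the 4 genes had a limma adjusted p under 0.05 only under alternative settings.

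For 12 h against 6 h, limma called 0 of the 38703 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 2451 genes, and voom weights gave 0 calls and 2434 genes at the unadjusted level. Requiring coverage of at least 20 reads in 3 libraries left 8564 genes, of which limma called 1, Zm00001d019241, at an adjusted p of 0.0307. The square-root scale gave the same gene at a limma adjusted p of 0.0233. Tested for a difference at any time, limma called 0 genes, with 2306 at an unadjusted p under 0.05, and with voom weights it called 1, Zm00001d019241, at an adjusted p of 0.0269. The same minimum of 20 reads and the minimum mean of 730 also called Zm00001d019241 at any time, at limma adjusted p of 0.0139 and 0.0417.

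Pairs of libraries from different times differed slightly more over all genes than pairs from the same time. Pairs of libraries from the same time had a mean dispersion of 67.3 (range 65.8 to 68.4 over 9 pairs), and pairs from different times 70.6 (range 69.3 to 72.2 over 27 pairs). Independent full reads would give 73 and partly overlapping reads less. In simulated reads with no replicate scatter, 12% of them cut at a window edge, pairs from the same time had 71.8. The real mean of 67.3 was lower, so no replicate scatter beyond read sampling was seen against that simulation. The share of cut reads in the real libraries was not measured, so the exact value for read sampling is not known. Correlations of log2 coverage over genes overlapped, with a mean of 0.738 (range 0.706 to 0.763) within a time and 0.735 (range 0.717 to 0.757) between times. The 6 h libraries correlated with each other at 0.719, 0.714 and 0.706, and with 0 h libraries at 0.717 to 0.747. By dispersion they were closer to each other, at 67.7, 68.4 and 67.5, than to any library of another time, at 69.3 to 72.2. The excess of 3.34 was larger than in any other of the 280 splits of the 9 libraries (exact p = 0.00357, the smallest these splits can give). In the 1669 genes with mean coverage of 2000 or more the means were 65.8 and 75.1, and in the 2272 genes under 200 they were 68.0 and 68.0. A log2 change of a given size gives a larger excess at higher coverage, so these means do not show in which genes changes lie. The dispersion tests were added after the gene tests had been seen.

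Log2 changes of the 21459 better-covered genes were only slightly alike between independent pairs of libraries. The reproducible part had an SD of 0.09 (95% interval 0.07 to 0.10) for 6 h against 0 h, 0.10 (0.09 to 0.11) for 12 h against 0 h and 0.11 (0.10 to 0.12) for 12 h against 6 h. Over genes, which are not independent replicates, the mean correlation between independent estimates of the same change was 0.030, 0.042 and 0.044. The reproducible variances were 0.0073, 0.0095 and 0.0112. Each was the highest of the 10 splits of its 6 libraries, against highest other values of 0.000382, 0.000455 and 0.000252, and 10 splits cannot give a share under 0.1.

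**Figure D2:**
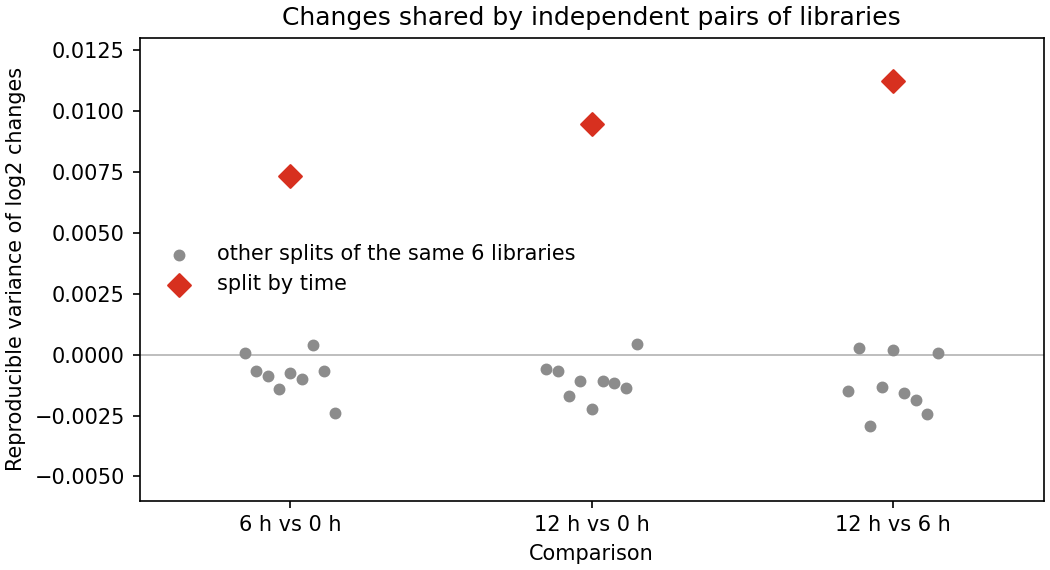
Reproducible variance of log2 changes over 21459 genes (y axis) for each comparison (x axis), with a diamond for the split by time and circles for the other splits of the same 6 libraries. The diamonds lie at 0.0073, 0.0095 and 0.0112, above all circles.

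Highly covered genes took a smaller share of coverage at both later times. The 10% of genes with the highest mean coverage held 23.4% ± 0.27 (SD, n = 3) of coverage at 0 h, 22.3% ± 0.238 (SD, n = 3) at 6 h and 22.4% ± 0.0276 (SD, n = 3) at 12 h. The difference from 0 h was -1.02 percentage points at 6 h and -0.946 at 12 h (exact permutation p = 0.1 for each, the smallest possible, adjusted 0.15). The difference of 0.0708 points between 12 h and 6 h was smaller than the spread at 6 h (exact permutation p = 0.7, adjusted 0.764). Across all 3 times the exact permutation p was 0.025 (adjusted 0.0333). The 100 highest genes held 0.973% ± 0.0128 (SD, n = 3), 0.923% ± 0.0151 (SD, n = 3) and 0.945% ± 0.0117 (SD, n = 3) at 0 h, 6 h and 12 h, with an exact permutation p of 0.00357 across times (adjusted 0.0143).

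The 10% with the lowest mean coverage held 1.75% ± 0.0566 (SD, n = 3) at 0 h, 1.91% ± 0.102 (SD, n = 3) at 6 h and 1.91% ± 0.0263 (SD, n = 3) at 12 h, and the exact permutation p across times was 0.0714. Total coverage was 37.4 ± 2.15 megabases (SD, n = 3) at 0 h, 31.0 ± 2.10 (SD, n = 3) at 6 h and 36.3 ± 0.47 (SD, n = 3) at 12 h. Every total at 6 h lay below every total at 0 h and at 12 h (exact permutation p = 0.1 for each, the smallest possible, adjusted 0.15). For 12 h against 0 h the exact permutation p was 0.4 (adjusted 0.48). Across times the exact permutation p for the total was 0.0143 (adjusted 0.0286). The labels give no batch or date for any library, so no comparison could be repeated within a batch, and a batch that followed the time points cannot be told apart from them.

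**Figure D3:**
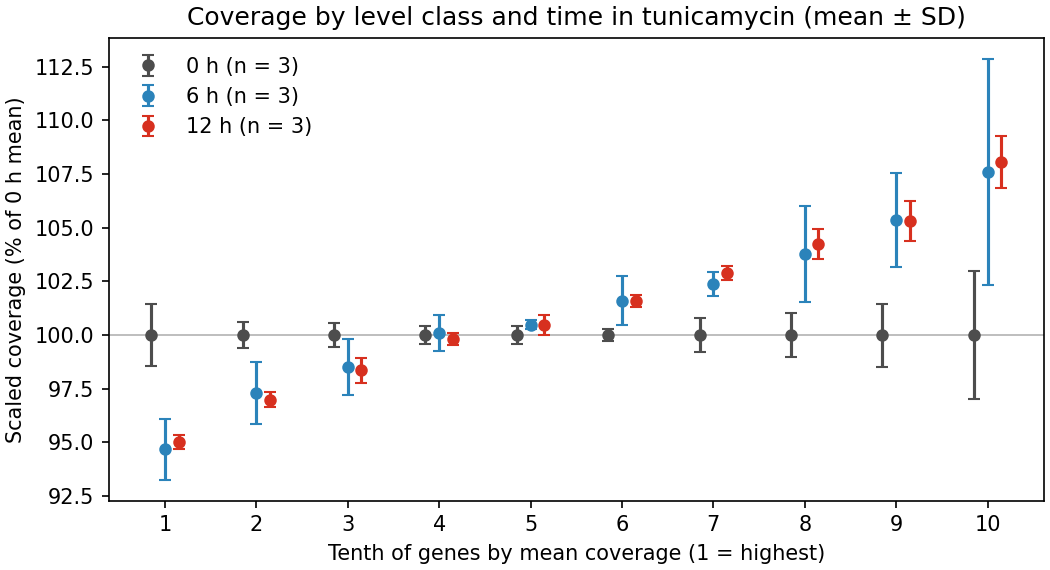
Scaled coverage as a percentage of the 0 h mean (y axis, which does not start at 0) for genes ordered by mean coverage in 10 classes of equal size (x axis, 1 is the highest), as the mean ± SD of 3 libraries at each time. The highest class lay at 94.7% ± 1.43 at 6 h, and the lowest at 108% ± 5.26 at 6 h and 108% ± 1.20 at 12 h.

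**Figure D4:**
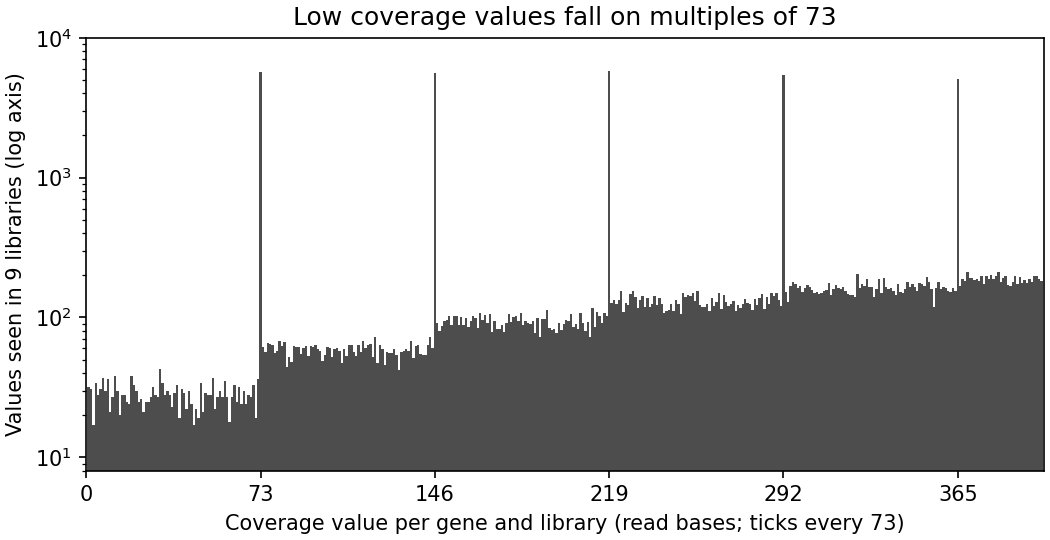
Number of values (y axis, log scale) at each coverage value per gene and library (x axis, read bases) over 9 libraries. Peaks stand at multiples of 73, with 5648 values at 73 itself.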

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

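The screen covered all 28 genes that the rule for named genes gave, and took those in which every library at 6 h lay on one side of the 0 h mean and every library at 12 h on the other. Its scope was settled after the values had been seen, and the genes had been picked for a low p between 6 h and 12 h, which favours this shape. For each gene below the limma adjusted p for 12 h against 6 h was 0.71, so none passed the threshold. Over the alternatives it ran from 0.118 to 0.853 for Zm00001d028512, 0.256 to 0.853 for Zm00001d039083, 0.351 to 0.853 for Zm00001d031431, 0.106 to 0.853 for Zm00001d005944 and 0.215 to 0.853 for Zm00001d021796.

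Zm00001d028512 had a mean coverage of 1442 ± 79.0 (SD, n = 3) at 0 h, 911 at 6 h and 1944 at 12 h, so that the change at 12 h exceeded that at 6 h by 1033.1. Zm00001d039083 had 1031 ± 197 (SD, n = 3) at 0 h, 662 at 6 h and 1564 at 12 h, 901.8 apart. Coverage of Zm00001d031431 was 882 ± 89.5 (SD, n = 3) at 0 h, 409 at 6 h and 1058 at 12 h, 648.6 apart. The opposite order was seen in Zm00001d005944, with 2219 ± 559.9 (SD, n = 3) at 0 h, 2973 at 6 h and 1654 at 12 h, a difference of -1319.1. It was also seen in Zm00001d021796, with 1902 ± 267 (SD, n = 3) at 0 h, 2656 at 6 h and 1516 at 12 h, a difference of -1140.3.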

How the results depend on the processing

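The square-root scale, voom weights, the pseudocount of 73, the minimum mean of 730 and every alternative for pooled measures were chosen after seeing the data. The count of genes called by limma was 0 under all other scalings, pseudocounts and thresholds run, and 0 with the replicate block in each comparison (2375, 2006 and 2495 genes at an unadjusted p under 0.05). Same-numbered libraries deviated together no more than others (correlations -0.022 to 0.019). No scatter beyond read sampling was seen within a time, so such small correlations cannot tell whether the numbers pair the libraries. For 6 h against 0 h the count was 1 on the square-root scale, and 0 to 1 leaving out each library. For 12 h against 0 h it was 2 on the square-root scale, and for 12 h against 6 h it was 1 there and 1 with at least 20 reads in 3 libraries. At any time it was 1 with that minimum, 1 on the square-root scale, 1 with voom weights, 1 with a mean of 730, and 0 to 1 leaving out each library, the 1 without 6 h replicate 1 (Zm00001d042506, limma adjusted p 0.00681). Fewer genes were tested under both minimums, and otherwise the cause was not tested. Of 640 log2 changes of named genes under alternatives, 638 kept direction and side of the threshold, 2 passed it and 0 reversed. That tally leaves out the square-root scale, which gives no log2 change and on which 3 of the named genes passed. Over alternatives the limma adjusted p ran from 0.00169 to 0.884 for Zm00001d042506 (6 h against 0 h), 0.047 to 0.986 for Zm00001d040216 and 0.047 to 0.999 for Zm00001d019241 (12 h against 0 h), and 0.0233 to 0.776 for Zm00001d019241 and 0.0816 to 0.853 for Zm00001d051105 (12 h against 6 h).

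For 6 h and 12 h against 0 h and 12 h against 6 h, the SD of reproducible log2 changes was 0.0867, 0.0873 and 0.0945 with a mean of 1500 or more, and 0.0818, 0.102 and 0.102 with 300 or more. Leaving out each library it ran from 0.0809 to 0.0890, 0.0935 to 0.103 and 0.0980 to 0.111 in that order. The dispersion excess ran from 2.98 to 3.59. The lower share of the highest genes was -0.692 and -0.605 points in the top 5% and -1.30 and -1.29 in the top 20%, for 6 h and 12 h against 0 h, sets of other sizes. Leaving out each library, the top 10% gave -1.15 to -0.879, -1.08 to -0.809 and, for 12 h against 6 h, -0.0395 to 0.197. Gene lists, motifs, location classes, GC correction, organellar peaks and the count-based tests were not run, and dropping the low filter removed nothing.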

Other observations

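The tests of library depth, of a level trend and of few genes behind the reproducible differences, and of the 280 splits, were chosen after the results had been seen, as were both batch checks. The other tests here were set before their results.

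Changes at 6 h and 12 h, each computed against separate 0 h libraries, had a covariance of 0.0028 over the 21459 better-covered genes. It ran from -0.00061 to 0.0075 over 54 choices of libraries, and the implied correlation of the reproducible changes was 0.336. Any deviation common to all 0 h libraries, such as a batch, enters both changes. The value therefore cannot tell such a deviation from a response shared by 6 h and 12 h.

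The lower share of coverage in the highest 10% of genes at 6 h and 12 h was weighed against 4 technical explanations. For depth, a single library could be compared with 12 h. The total of 0 h replicate 2 was below every 12 h total, but its share was 0.905 points above the highest 12 h share. Every 6 h total lay below every 0 h total, so depth cannot be told apart from time at 6 h. Depth therefore stays open for 6 h, and the check at 12 h rests on that library alone. With each library scored on genes ranked without it, the lowest 0 h share still exceeded the highest later share by 0.577 points, and without the 100 highest genes by 0.502 points. A batch of preparation or sequencing that followed the time points stays open, since 0 libraries carry a batch or date label. Nuclei quality was not tested, nor was any biological explanation.

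For the reproducible differences between time points, only 1 of the 280 splits, the real one, gave an excess as large (3.34, highest other 1.82). By dispersion pooled over times, libraries of a time were thus more alike than a random grouping gives. By log2 correlation, the 6 h libraries were no closer to each other than to libraries of other times. That correlation makes no allowance for read noise, which is larger at the lower totals of 6 h. By dispersion, pairs of 6 h libraries (67.5 to 68.4) lay below every pair of a 6 h library with another time (69.3 to 72.2). Removing the trend with coverage level from each library left 93.8% of the reproducible variance on average, so a level trend does not account for most of it. For 6 h and 12 h against 0 h, 87.6% and 91.0% were left, while 12 h against 6 h had almost no trend to remove. It was also computed in level classes of mean coverage 300 to 730, 730 to 1500 and 1500 or more. The ratio of the highest to the lowest class was at most 1.98, so the variance was not confined to the highest class. Genes under 300 were in no class. The lowest class at 6 h against 0 h was weakest, with a variance of 0.0038 and an SD over library pairs of 0.0032. Whether a few strongly changing genes within a class carry the variance was not tested, since class means cannot show it. Genes with identifier numbers 2, 3, 5 or 10 apart shared on average 15.9% of the reproducible variance. It was computed over 34527 genes of mean coverage 300 or more with the level trend removed. The 12 values ran from -3.92% to 50.3%, and adjacent genes shared 30.8%. At 20 and 50 apart the mean was 3.97%, with values from -14.8% to 32.8%. With values this scattered, a regional change stays open. A preparation or batch that followed the time points, with 0 labelled libraries, cannot be told apart from the hypothesis that many genes may change slightly under tunicamycin.

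With 0 called genes in the real split, counts of called genes over other splits carry no information on chance, since every split reaches 0. That holds for all 10 splits of the 6 libraries in each pair of times (real 0, highest other 0) and for 100 of 100 drawn splits at any time (real 0, highest other 3). Counts at an unadjusted p under 0.05 were 2365, 2003 and 2451 in the real splits and at most 1962, 1596 and 2076 in the others, and 10 splits are too few for a share under 0.05. At any time, for genes at an unadjusted p under 0.05, 1 of the 100 splits, the real one with 2306 genes, reached that number, and the highest other was 2012.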
